A study of Homo sapiens with 11 samples.

How the data were processed

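The 11 libraries came from H1299 cells transfected with 5 µg of construct DNA and selected in neomycin at 800 µg per ml for 14 days, per the labels' protocols. RNA was made into Lexogen QuantSeq 3′ libraries and sequenced as single 75 bp reads on a NextSeq 500. The deposited values are estimated counts per Ensembl gene, one column per library, and they were whole numbers as deposited. Per the submitters' processing notes, which give no order or settings, the tools were Bowtie2, RSEM 1.2.12, which estimates counts and shares out reads with several matches, and DESeq2, on genome build hg38. Whether counting used strand is not given in the sources used here. Each column was matched to its library by title, and hotspot, codon 72 form and batch were taken from the labels. No further columns of values were present.

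The table held 45965 genes, of which 20641 had no count in any library. Annotation came from GENCODE 29 (hg38), which holds 42551 of the gene IDs, and 95.6% of the transcripts listed in the table are there in the same version. Coordinates are 1-based. Totals were 8346926 to 12829560, TMM factors 0.979 to 1.03, and mitochondrial genes took 4.03% to 5.52% of counts. For genes with a mean of at least 10 CPM the median SE of the log2 fold change was 0.113 for R72 on R175H, 0.166 for R72 on R273H and 0.128 for the hotspot comparison. The counts of replicate pairs differed by more than sampling noise in all 12 pairs (chi-square per degree of freedom 4.24 to 20.1), so no library was counted as a duplicate. The first principal components held 23.6% and 13.9% of the variance.

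Differential expression used edgeR 4.0.16 in R 4.3.3. The call to DESeq2 rounds its input, which left these whole numbers as they were. Genes were kept with filterByExpr on the 4 groups (minimum count 10, minimum total 15), which left 16324. Libraries were scaled by TMM and fitted with the robust quasi-likelihood method, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with 0.05 as the threshold. The effect of R72 over both mutants came from a model of batch, hotspot and codon 72 form. The R72 effects within R175H and R273H, their difference and the hotspot effect within P72 came from a model of the 4 groups and batch over all 11 libraries. The batch term itself was called for 1504 genes.

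The genes named were PPARGC1A, and for 3 comparisons the 10 highest and 10 lowest fold changes among called genes with a mean of at least 10 CPM and a named symbol, without clone, LINC, antisense or pseudogene names. For the other comparisons it was 5 each way, and from each gene list up to 4 members with the smallest p. Some of the genes this rule took are not reported here. The designs, this rule, the alternatives, 23 gene lists and 6 marker lists were fixed before the data were examined. The gene lists cover the PGC-1α pathway, OXPHOS complex I, complexes II to V, mitochondrially encoded mRNA, mitochondrial ribosome, TCA cycle, glycolysis, fatty acid oxidation, canonical p53 targets, mevalonate synthesis, NRF2, epithelial and mesenchymal markers, matrix and adhesion, proliferation, stress response, hypoxia, interferon, NF-kB, immediate early genes, reported gain-of-function targets, cytosolic ribosomal proteins and replication-dependent histones. They were written from general knowledge and some share members. The marker lists cover fibroblast, leukocyte, endothelial, neuroendocrine, squamous, and hepatocyte and kidney cells. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry (limma 3.58.1), adjusted over the lists of a comparison. No camera call held with an estimated correlation.

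Alternatives were RLE scaling, library totals, no filter, a filter at 10 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, no batch term, the replicate number as a block, each library left out in turn, batch b2 alone, and other models. A correction for GC content was added after seeing the data, alone and in batch b2. It fits each library's deviation of log2 CPM on the GC content of the last 500 nt of a gene's transcripts with a natural spline of 5 degrees of freedom and enters the fit as offsets. A GC value was had for 16029 of the genes tested and for all 133 genes lower with R72 on R175H.

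The procedure was tested on simulated counts with 200 changed genes. For R72 over both mutants (15862 genes) it recovered 93% of changes of 1.5-fold and 100% of 2-fold, with 9 false among 202 calls. For R72 within R175H (15942 genes) it recovered 68% and 97%, with 25 false among 190 calls, a share above the nominal 5%. For the hotspot comparison (15885 genes) it recovered 65% and 97%, with 13 false among 175. With a GC trend added to the R175H R72 libraries (15929 genes) 298 of 467 calls were false, and 12 of 188 after the correction. The added trend was the same straight line in each of these libraries and absent from all others. In the data their slopes were 0.071, -0.078 and -0.049 log2 units per 10% GC, and other groups had slopes too. This simulation therefore does not show how well the correction works on the trends of these data. Of 10 simulated lists the 1 shifted list of 30 genes, by 1.3-fold, was called by camera and 0 of 9 unchanged lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.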

Results

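Messenger RNA was measured by 3′ tag sequencing in 11 libraries of H1299, a human lung carcinoma line that makes no p53 of its own. The cells had been stably transfected with mutant p53 carrying either of 2 hotspot mutations, R175H or R273H, on either form of the codon 72 polymorphism, proline (P72) or arginine (R72). The groups held 3 R175H P72, 3 R175H R72, 4 R273H P72 and 1 R273H R72 libraries. The labels put 4 libraries in batch b1 (R175H R72 replicate 1 and R273H P72 replicates 2, 3 and 4) and 7 in batch b2. The total per library lay between 8346926 and 12829560 estimated counts, and 19540 to 20489 genes had a count. The labels do not say that replicates were separate cultures or separately selected lines, so p-values here measure only the spread between libraries, which may be technical. The title of the series names tumour metabolism, metastasis and PGC-1α, which PPARGC1A encodes.

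PPARGC1A (ENSG00000109819), the gene of a coactivator of mitochondrial biogenesis, did not pass the test in any of the 5 comparisons. It lay between 2.64 and 4.57 CPM (counts scaled by library size), from 22 to 49 counts per library. Its log2 fold change of R72 over P72 was -0.12 (SE 0.27) within R175H and 0.74 (SE 0.38) within R273H, with adjusted p-values of 0.899 and 0.678 (edgeR quasi-likelihood test, Benjamini-Hochberg). Their difference was 0.87 (SE 0.51, adjusted p = 0.595), and R273H over R175H within P72 was -0.38 (SE 0.31, adjusted p = 0.459). At this depth a change in PPARGC1A of these sizes was not detectable.

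**Figure D1:**
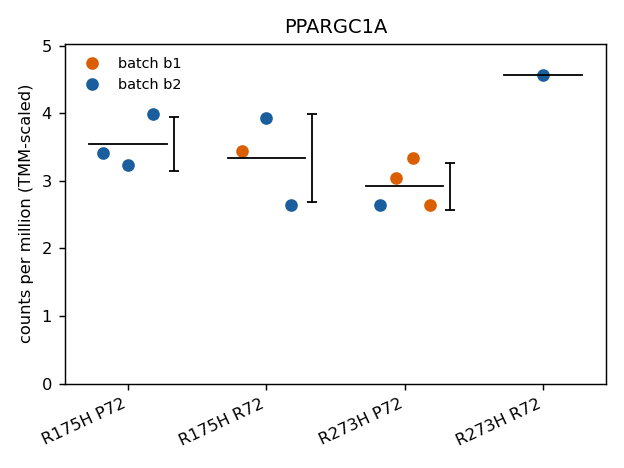
TMM-scaled CPM of PPARGC1A in each library, by group, with the batch in colour, the group mean as a line and its SD as a bar. The values lie between 2.64 and 4.57, and the groups overlap or differ by less than the test could call.

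The first comparison asked which genes differed between the codon 72 forms on R175H. KLF16 (ENSG00000129911, hg38 chromosome 19, 1852399 to 1863568), a zinc finger transcription factor, was 2.995-fold lower with R72 (log2 fold change -1.58, SE 0.17, adjusted p = 6.83e-05, 3 against 3 libraries). ALKBH7, a mitochondrial dioxygenase, was 2.74-fold lower and ATP5D, the delta subunit of ATP synthase, 2.28-fold lower. EML3, a microtubule-associated protein, was 2.22-fold lower and SGTA, a cochaperone, fell by 0.97 on the log2 scale. The autophagy protease gene ATG4D went from 27.6 to 8.11 CPM (log2 fold change -2.00, SE 0.32), and it shares exonic sequence with KRI1 on the other strand. RPL18, C19orf70, MLST8, a subunit of the mTOR complexes, and COPE, a coatomer subunit, fell by 1.27, 0.97, 0.94 and 0.91 on the log2 scale. ALKBH7, EML3, MLST8, RPL18 and C19orf70 also overlap tested genes of the opposite strand, and the sources used here do not say whether counting used strand.

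Among genes that rose with R72 on R175H, EFNB2, the ephrin-B2 ligand, was 1.77-fold higher (SE 0.17 on the log2 scale, adjusted p = 0.0149). TMEM200A was 1.63-fold and the serine protease gene PRSS23 1.51-fold higher, with adjusted p-values of 0.00373 and 0.00227. BDNF, a neurotrophin, rose from 28.9 to 42.2 CPM and SEMA3C, a secreted semaphorin, from 30.3 to 41.5 CPM. The others named by the rule were MT-TP, QSOX2, SSFA2, SPTLC1 and SLC44A1, with log2 fold changes of 0.55 to 0.62. TRPM8 (ENSG00000144481, hg38 chromosome 2, 233917398 to 234019522), a cold-sensing ion channel gene, was chosen after its values were seen because it lies below 10 CPM. It had 8.47 to 9.14 CPM in the 3 R175H R72 libraries and 0.403 to 1.99 CPM in the other 8 (log2 fold change 3.52, SE 0.31, adjusted p = 1.262e-06).

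Of the 16324 genes tested, 52 were higher and 133 lower with R72 on R175H, and 2223 had an unadjusted p under 0.05, where chance alone gives 816. Scaling by library totals gave 65 higher and 105 lower. Of the lower genes, 33.1% lay on chromosome 19, which holds 7.47% of the genes tested, and their 3′ ends had a median GC content of 60.6% against 41.4% over all genes. The slope of expression on GC content was 0.013 to 0.037 log2 units per 10% GC in the R175H P72 libraries and 0.071 in R175H R72 replicate 1, and -0.078 and -0.049 in R175H R72 replicates 2 and 4. With each library's GC trend removed, 35 genes were called, among them KLF16, ALKBH7, ATP5D, EML3, SGTA, ATG4D, TMEM200A, QSOX2 and PRSS23 of those above. Without a batch term 6 genes were called, KLF16 (adjusted p = 0.0147) being the one of these that the rule named, without R175H R72 replicate 2 only 24, without R175H P72 replicate 2 only 52, and without R273H P72 replicate 3 only 108. KLF16, ALKBH7, ATP5D, EML3, SGTA and MLST8 were called whichever library was left out.

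**Figure D2:**
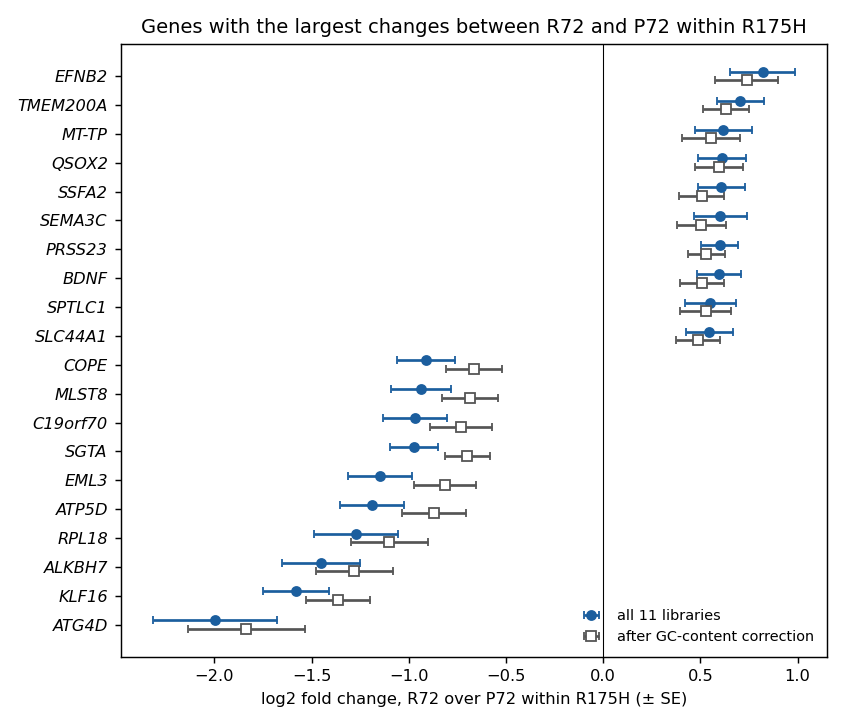
Log2 fold change of R72 over P72 within R175H, with its SE, for the 10 highest and 10 lowest genes of the naming rule, from all 11 libraries and after removal of each library's GC trend. ATG4D, at -2.00, and KLF16, at -1.58, lie farthest from 0.

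**Figure D3:**
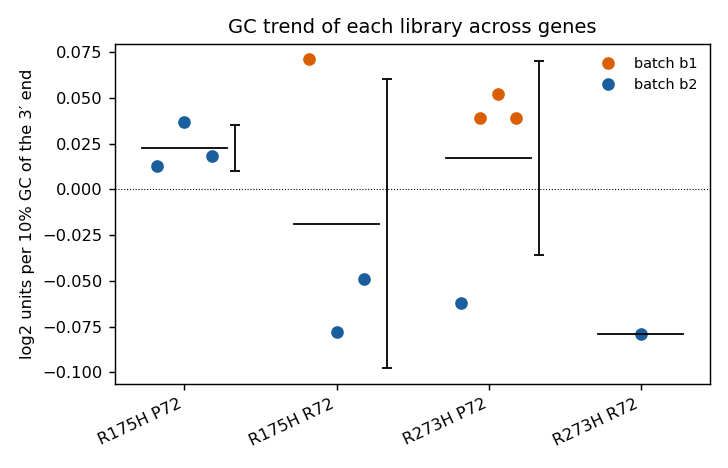
Slope of each library's expression on the GC content of the 3′ end, across 9557 genes, by group, with the batch in colour, the mean as a line and its SD as a bar. R175H R72 replicates 2 and 4, R273H P72 replicate 1 and the R273H R72 library have slopes below 0.

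By gene list, 4 of 38 subunit genes of OXPHOS complex I fell with R72 on R175H, NDUFV1 (log2 fold change -0.64), NDUFS7 (-0.54), NDUFA13 (-0.73) and NDUFA11 (-0.35). Adjusted over the list alone, 1 was higher and 5 lower, and the camera test of the list gave an adjusted p of 0.0814. After GC correction the values of the 4 genes were -0.435, -0.184, -0.537 and -0.211, with 0 called, and with each of the 11 libraries left out in turn they were called in 10, 5, 6 and 5 fits. Of 43 cytosolic ribosomal protein genes, RPS19 and RPL18 fell (0 higher and 7 lower adjusted over the list alone), and 37 had negative values. That list was lower by camera (adjusted p = 6.53e-08) and not with an estimated correlation (adjusted p = 0.607). All 13 mitochondrially encoded mRNAs had positive values, 0 passed edgeR's test over all genes (6 at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma-voom) and 5 were higher adjusted over the list alone. The list was higher by camera (adjusted p = 1.27e-05), not with an estimated correlation (adjusted p = 0.607). Camera also called the extracellular matrix and adhesion, mevalonate, reported mutant p53 gain-of-function target and mesenchymal lists higher, with adjusted p-values of 0.00972, 0.015, 0.0152 and 0.0357. With an estimated correlation the adjusted p was 0.607 for each of them. Over all genes edgeR and limma-voom called 0 members, and DESeq2 called 3 matrix genes and 1 of each other list, with 9, 9, 6 and 4 at an unadjusted p under 0.05. Adjusted over the list alone, 3 matrix, 3 mevalonate and 1 gain-of-function members were higher and 1 gain-of-function member lower.

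Single members of other lists passed on R175H. ECI1 (fatty acid oxidation) and MRPS34 (mitochondrial ribosome) fell by 0.43 and 0.60 on the log2 scale, and ATP5D was the member of complexes II to V that passed. BUB1, a mitotic checkpoint kinase, rose by 0.42 and PLOD2, a collagen hydroxylase of the hypoxia list, by 0.46. In the interferon list ISG15 fell by 0.89 and B2M rose by 0.51. Adjusted over the list alone, fatty acid oxidation had 1 higher and 3 lower, and the other 5 of these lists kept the counts above. Of the list members called on R175H, ATP5D alone was called after GC correction. With each of the 11 libraries left out in turn, BUB1 ran from 0.26 to 0.47 and B2M from 0.3 to 0.59. BUB1, B2M and PLOD2 were called in 5 of these fits each, ECI1 in 8, MRPS34 and ISG15 in 9 each and ATP5D in all 11. Of the 32 tested genes of the PGC-1α pathway list, 0 passed edgeR's test over all genes (7 at an unadjusted p under 0.05, 0 called by DESeq2 or limma-voom) and 1 was lower adjusted over the list alone. SIRT3, a mitochondrial deacetylase, had the smallest p there (log2 fold change -0.54, SE 0.14, adjusted p = 0.0654). No member of the TCA cycle, glycolysis, canonical p53 target, NRF2, epithelial, stress response, NF-kB, immediate early or histone lists passed over all genes by edgeR. Of the 29 stress response genes DESeq2 called 4 and limma-voom 1, with 15 at an unadjusted p under 0.05. Of the 23 NRF2 genes DESeq2 called 2 and limma-voom 0, with 6 at an unadjusted p under 0.05. In the rest of these lists both tools called 0. Adjusted over the list alone, the stress response list had 4 higher and 4 lower and the NRF2 list 2 higher and 1 lower.

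The same question on R273H set 1 R72 library against 4 P72 libraries, so the single library was assumed to vary like the other groups. NDUFB7, a complex I subunit, had a log2 fold change of -0.89 (SE 0.27), EBP and ACAT2, of cholesterol synthesis, -0.63 (SE 0.13) and -0.64 (SE 0.14), and ITGA3, an integrin, 0.52 (SE 0.12). Their adjusted p-values were 0.377, 0.149, 0.149 and 0.149, and edgeR called 0 genes, with 1265 at an unadjusted p under 0.05. DESeq2 called 112 genes and limma-voom 2. Of the lists, mevalonate synthesis and the growth factor and immediate early genes were lower by camera (adjusted p = 0.00127 and 0.00132), with 3 and 2 members lower adjusted over the list alone. Neither held with an estimated correlation (adjusted p = 0.681 for both).

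The difference between the R72 effects on R273H and on R175H was called for 5 genes, of which TRPM8, below 10 CPM, was named after its values were seen. TRPM8 differed by -4.38 (SE 0.63, adjusted p = 0.0101). TUBA1B, an alpha-tubulin, differed by -1.01 (SE 0.18) and SMIM11B by -1.28 (SE 0.23), and both have near-identical copies that can share reads. MAF1, a repressor of RNA polymerase III, differed by 1.08 (SE 0.18) and the small nucleolar RNA host SNHG25 by 0.98 (SE 0.16). After GC correction the differences of TUBA1B and SMIM11B hardly moved (-1.023 and -1.265), while those of MAF1 and SNHG25 shrank to 0.887 and 0.798. DESeq2 called 138 genes and limma-voom 12, and TRPM8 was the gene called after GC correction (adjusted p = 0.0134). Apart from TRPM8, the difference was not called for KLF16, ATP5D or the other genes named on R175H, so their effects were not shown to be unequal on R273H. Of the lists, mevalonate synthesis, gain-of-function targets, proliferation and immediate early genes were lower by camera in this difference and cytosolic ribosomal proteins higher, with adjusted p-values of 5.8e-05, 0.00751, 0.0192, 0.0311 and 8.29e-05. With an estimated correlation the adjusted p was 0.751 for all but proliferation, where it was 0.813. Adjusted over the list alone, 5 mevalonate and 2 proliferation members were lower and 1 gain-of-function member higher.

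The comparison of 4 R72 with 7 P72 libraries fitted 1 R72 effect, assumed to be common to both hotspot mutants. Of the 4 R72 libraries 3 were R175H, so a call here does not show that a gene changed on R273H. TSPAN4 (ENSG00000214063, hg38 chromosome 11, 842808 to 867116), a tetraspanin, was 1.499-fold lower with R72 (log2 fold change -0.58, SE 0.08, adjusted p = 0.000923). GPX4, which reduces lipid peroxides, and ARFGAP1, a regulator of Golgi transport, were 1.44-fold lower. ATRIP, a partner of the checkpoint kinase ATR, NDUFB7, SCAND1 and ASL, an enzyme of the urea cycle, had log2 fold changes of -0.74, -0.70, -0.70 and -0.66. UBE2M and MRPL54 fell by 0.51 and 0.50 on the log2 scale. BCYRN1, a noncoding RNA related to Alu repeats whose reads may come from other copies, made up 0.644% to 1.31% of counts and fell by 0.53. PMEPA1, an antagonist of TGF-beta signalling, was 1.35-fold higher, SFRP1, a Wnt antagonist, 1.33-fold and CXADR, a junctional receptor, 1.29-fold higher. CD82, a tetraspanin, was 1.27-fold higher, with 142 against 99.1 CPM on R175H and 158 against 159 CPM on R273H.

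In all, 6 genes were higher and 29 lower over both mutants, against 6 and 16 when scaled by library totals, and 1736 had an unadjusted p under 0.05. TSPAN4 was called whichever library was left out, while PMEPA1, CXADR, CD82, ASL and BCYRN1 were called in 2 of those 11 fits each. After GC correction 9 genes were called, TSPAN4 (adjusted p = 0.0323) and CD82 (adjusted p = 0.0359) being those of the named genes. Some others lost the call with folds that hardly moved, such as PMEPA1 (0.437 to 0.453), SFRP1 (0.41 to 0.391) and ASL (-0.657 to -0.62). The folds of others shrank, such as SCAND1 (-0.698 to -0.413) and ARFGAP1 (-0.529 to -0.361). Without a batch term 2 were called, neither of them among the genes named for this comparison (TSPAN4 -0.592, SE 0.147, adjusted p = 0.423). The list of mitochondrially encoded mRNAs was higher by camera (adjusted p = 4.16e-06, and 0.583 with an estimated correlation), with 13 of 13 positive and 6 higher adjusted over the list alone. That of cytosolic ribosomal proteins was lower by camera (adjusted p = 7.65e-05, and an adjusted p of 0.638 with an estimated correlation), with 3 lower adjusted over the list alone. Camera called the matrix and mesenchymal lists higher (adjusted p = 0.000498 and 0.0174), not with an estimated correlation (adjusted p = 0.204 for both). By fry the adjusted p was 0.0173 for the mesenchymal list and 0.073 for the matrix list. It was 0.302 by fry for the mitochondrially encoded and 0.354 for the ribosomal protein list. Of the 24 matrix and 21 mesenchymal genes edgeR called 0 over all genes, where DESeq2 called 1 mesenchymal gene. Adjusted over the list alone, 2 mesenchymal members were higher. Of complex I, NDUFB7 fell over all genes, with 4 lower adjusted over the list alone. Of the PGC-1α list 0 of 32 passed edgeR's test over all genes (4 at an unadjusted p under 0.05, 0 called by DESeq2 or limma-voom) and 2 were lower adjusted over the list alone.

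The hotspot comparison asked how R273H cells differed from R175H cells on P72. CYR61 (ENSG00000142871, hg38 chromosome 1, 85580761 to 85583962), a secreted matricellular protein, was 3.51-fold higher in R273H (log2 fold change 1.81, SE 0.28, adjusted p = 0.00651, 4 against 3 libraries). ADM, the adrenomedullin gene, was 2.63-fold, the netrin receptor gene NEO1 2.4-fold and ANKRD1, a stress-induced cofactor, 2.27-fold higher. MT-ND6 rose by 1.74, TMEM2 by 1.36 and MT-ATP8, which overlaps MT-ATP6, by 1.19 on the log2 scale. CDK2AP1 and JKAMP had fitted log2 fold changes of 1.52 and 1.24, and 1.529 and 1.242 in batch b2 alone, where they rest on R273H P72 replicate 1 (32.3 and 89.5 CPM). Their means over both batches were 11.6 against 11.2 and 43 against 37.8 CPM, and CDK2AP1 overlaps the more abundant AC068768.1 on its own strand. HBD (ENSG00000223609, hg38 chromosome 11, 5232678 to 5243657), the delta-globin gene, was 2.94-fold lower in R273H (log2 fold change -1.56, SE 0.09, adjusted p = 1.295e-09). UPP1, a uridine phosphorylase, was 2.56-fold lower, PDLIM7, a cytoskeletal adaptor, 2.33-fold and CALB2, the calretinin gene, 2.32-fold lower. CRIP2 was 2.46-fold lower, and MGAT5B and LRRC37B fell by 1.27 and 1.25 on the log2 scale. The largest fitted fall among the named genes was that of LRRC75A, 15.9-fold, with an SE of 0.83 and an overlap with the far more abundant LRRC75A-AS1. RPL28 and PHKG1, which overlaps SUMF2, fell by 2.34 and 2.19.

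Of the genes tested, 1135 were higher and 1241 lower in R273H, and 4533 had an unadjusted p under 0.05. Because 3 of the 4 R273H P72 libraries were of batch b1 and all R175H P72 libraries of b2, the comparison leans on the batch term and on R273H P72 replicate 1. In batch b2 alone 866 genes were called, 419 higher and 447 lower, without R273H P72 replicate 1 it was 1253 and without R175H R72 replicate 1 it was 1214. Without the batch term the fitted values were 0.92 for CYR61, 0.12 for CDK2AP1, 0.20 for JKAMP, -2.46 for LRRC75A, -0.78 for CRIP2 and -1.45 for RPL28, none of them called, while CYR61, CDK2AP1, CRIP2 and RPL28 were called in batch b2 alone. LRRC75A, PHKG1 and JKAMP were not called in batch b2 alone, which has fewer libraries, at log2 fold changes of -4.179, -1.901 and 1.242. HBD, NEO1, TMEM2, ANKRD1, MT-ND6, UPP1, PDLIM7, MGAT5B, LRRC37B and CALB2 were called in each of these fits and whichever library was left out.

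**Figure D4:**
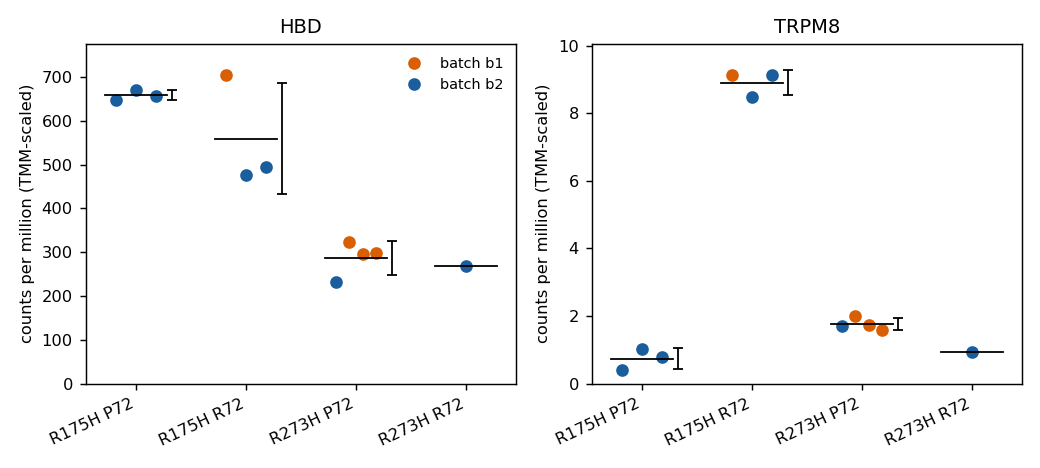
TMM-scaled CPM of HBD and TRPM8 in each library, by group, with the batch in colour, the group mean as a line and its SD as a bar. HBD lies between 477 and 704 in the R175H libraries and between 231 and 322 in the R273H libraries, and TRPM8 between 8.47 and 9.14 in R175H R72 and at most 1.99 elsewhere.

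Of 24 tested genes of mevalonate and cholesterol synthesis, 13 rose in R273H and 0 fell by edgeR (14 and 0 adjusted over the list alone), and 6 had negative values. Those that rose included ACAT2 (1.81-fold), HMGCS1 (1.68-fold) and EBP (1.65-fold). Camera gave the list an adjusted p of 5.41e-07, against an adjusted p of 0.605 with an estimated correlation and 0.0273 by fry. Of 34 proliferation genes 15 rose and 2 fell (18 and 2 adjusted over the list alone). MCM3 and MCM4, of the replicative helicase, were 1.88-fold and 1.54-fold higher and RRM1, of ribonucleotide reductase, 1.78-fold higher, while AURKB and UBE2C fell by 0.37 and 0.44 on the log2 scale. The adjusted p was 6.73e-06 by camera, 0.691 with an estimated correlation and 0.0305 by fry. All 13 mitochondrially encoded mRNAs had positive values and 6 rose (10 adjusted over the list alone). The adjusted p of this list was 4.38e-06 by camera, 0.691 with an estimated correlation and 0.094 by fry. Of 43 cytosolic ribosomal protein genes, 16 fell and 0 rose by edgeR (21 and 1 adjusted over the list alone), such as RPL12 (log2 fold change -0.53). Their adjusted p was 3.97e-07 by camera, 0.691 with an estimated correlation and 0.0617 by fry. In batch b2 alone 7 mevalonate and 8 proliferation genes rose and 8 ribosomal protein genes fell. R273H P72 replicate 1, of that batch, had a GC slope of -0.062, and after GC correction over all libraries 11 mevalonate and 14 proliferation genes rose and 13 ribosomal protein genes fell.

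**Figure D5:**
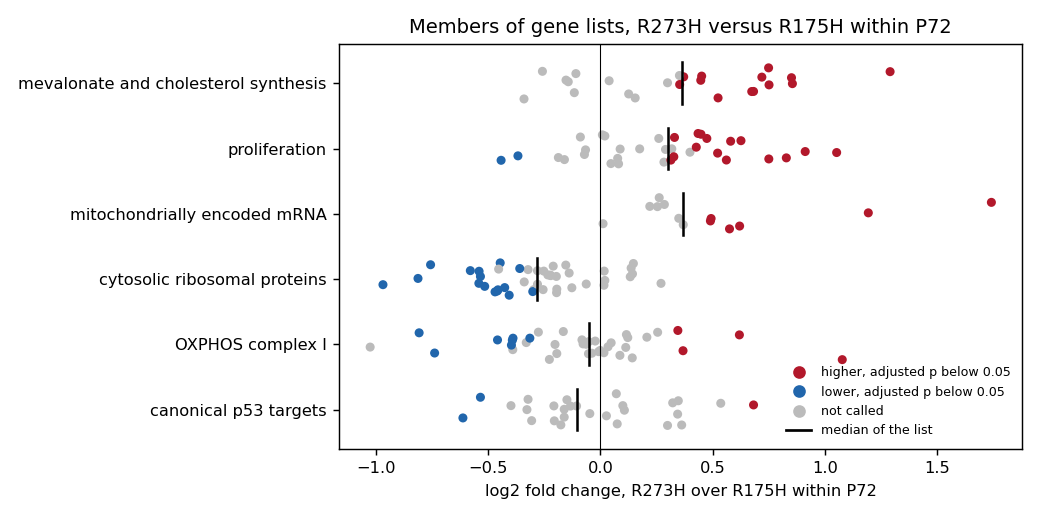
Log2 fold change of R273H over R175H within P72 for each tested member of 6 gene lists, coloured by the edgeR call, with the median of the list as a bar. Of the mevalonate genes 13 rose and of the ribosomal protein genes 16 fell.

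Apart from the mitochondrially encoded mRNAs above, energy metabolism genes moved both ways in the hotspot comparison, and camera called none of the lists that follow here. Of complex I 4 of 38 rose and 7 fell (4 and 10 adjusted over the list alone), with NDUFV1 at -0.81 and NDUFB3 at 1.08. Of complexes II to V 3 of 38 rose and 5 fell (6 and 5 adjusted over the list alone), with CYC1 at -0.64 and COX6C at 0.57. Of the PGC-1α list 1 of 32 rose, the coactivator PPRC1 (0.50), and 5 fell (1 and 5 adjusted over the list alone), such as the peroxiredoxin PRDX5 (-0.66). Of the mitochondrial ribosome list 3 of 38 rose and 1 fell, and of the TCA cycle list 1 of 24 rose, ACLY, and 3 fell, such as DLST (-0.56), with the same counts adjusted over the list alone. Glycolysis had 3 of 23 higher and 5 lower (4 and 6 adjusted over the list alone), with GAPDH at -0.64 and the lactate transporter SLC16A1 at 0.58. Fatty acid oxidation had 3 of 25 higher and 3 lower (3 and 4 adjusted over the list alone), with ECI1 1.9-fold lower and ACSL4 at 0.53. NDUFB3, COX6C and ACSL4 had values of 1.012, 0.594 and 0.644 in batch b2 alone, all called, against 0.15, 0.138 and 0.009 without the batch term, none called.

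Of 29 stress response genes 4 rose and 9 fell (6 and 9 adjusted over the list alone), with TRIB3, SHMT2 and SESN2 at -0.97, -0.92 and -0.61 and the cystine transporter SLC7A11 at 0.70. Of 23 NRF2 genes 3 rose and 5 fell (4 and 7 adjusted over the list alone), and the ferritin genes FTL and FTH1 had values of -0.64 and -0.46. Of 27 canonical p53 targets 1 rose, SUSD6, and 2 fell, SESN2 and BBC3, with the same counts adjusted over the list alone. Of 29 reported gain-of-function targets 7 rose and 1 fell (8 and 1 adjusted over the list alone), with ABCB1, a drug efflux pump, at 0.66 and RHOA at -0.74. That list was higher by camera (adjusted p = 0.00392), not with an estimated correlation (adjusted p = 0.691) or by fry (adjusted p = 0.0628). The hypoxia list had 4 of 20 higher and 1 lower (the same adjusted over the list alone), with P4HA2 at 0.76 and DDIT4 at -0.57. The interferon list had 1 of 30 higher, B2M (0.85), and 3 lower, such as ISG20 (-1.11), also adjusted over the list alone. The NF-kB list had 3 of 21 higher, SAA1, BIRC3 and ICAM1, also adjusted over the list alone, and SAA1 went from 0.495 to 3.18 CPM. The immediate early list had 2 of 25 higher, EGR1 (0.46) and KLF6 (0.43), and 1 lower, DUSP1 (-0.96), with 2 and 2 adjusted over the list alone. Of 11 replication-dependent histones 0 passed by edgeR, with 0 at an unadjusted p under 0.05 and 0 called by DESeq2 or limma-voom.

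For adhesion and cell state, 3 of 24 matrix genes rose, CYR61 among them, and 6 fell (7 and 7 adjusted over the list alone), with COL6A1, ITGA3 and MMP1 at -0.69, -0.53 and -1.88. Of 21 mesenchymal genes 2 rose, CDH2 (0.50) among them, and 4 fell, such as VIM (-0.65) and MMP14 (-0.42), also adjusted over the list alone. Of 9 epithelial genes 1 fell, PKP3 (-0.60), with 1 higher and 1 lower adjusted over the list alone. Of the list members named for the hotspot comparison, NDUFV1, GAPDH, ACLY, SUSD6, BBC3, PKP3, COL6A1, ITGA3 and KLF6 were also not called without the batch term. After GC correction MMP14 (-0.289), PKP3 (-0.357), BBC3 (-0.364) and PAX8 (-0.756) were not called. In batch b2 alone, with fewer libraries, PPRC1, ACLY, SUSD6, BBC3, FTH1, PKP3, CDH2, BIRC3, ICAM1, DUSP1, KLF6, EGR1, NPHS1 and PAX8 were not called, each with the sign it had over all libraries. Median and mean differed in sign in the complex II to V, TCA cycle, stress response, mesenchymal and immediate early lists, and the lists that camera called had median, mean and test of one sign in all 5 comparisons.

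Of the fibroblast, leukocyte and endothelial lists 1, 5 and 2 genes could be tested, and no member passed by edgeR in any comparison. Of the neuroendocrine, squamous and hepatocyte and kidney lists 4, 3 and 3 could be tested. In R273H SYP rose from 1.62 to 3.52 CPM and NPHS1 from 2.4 to 4.52 CPM, while KRT15 and PAX8 fell by 0.69 and 0.92 on the log2 scale, with the same calls adjusted over the list alone.

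The R72 comparison on R175H and the hotspot comparison share the 3 R175H P72 libraries, which are the reference of both. ATP5D, ECI1 and SHMT2 had negative and B2M and BUB1 positive values in both. Of the genes lower with R72 on R175H, 116 were also lower in R273H, and 44 of the higher genes were also higher. Across genes with a mean of at least 10 CPM, which are not independent replicates, the fold changes correlated at r = 0.74. In 20 simulations of unchanged groups r was 0.59, and at most 1 gene was called in both comparisons. Over the same genes the covariance was 0.058, against 0.016 in the simulations, which leaves 0.041. Part of the excess may come from the shared libraries, since 3 libraries cannot be divided into parts of at least 2. The fold changes of both comparisons also ran with GC content across genes (r = -0.37 for R72 on R175H and -0.28 for the hotspots). The simulations hold no GC trend, so this may add to the excess as well, which was not tested.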

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

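The GC-content correction and the test of the genes still called after it were chosen after the result was seen.

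Genes lower with R72 on R175H were rich in GC and in chromosome 19 genes. With each library's GC trend removed, 24 genes, 18% of the 133, stayed lower past the threshold. Their median log2 fold change was -0.80 before and -0.63 after (SE 0.12 and 0.11). This argues against the GC trend as fitted being their whole cause. The 24 were picked by this same test, so their sizes are inflated, and GC effects that the fitted trend misses may remain. For the other 109 the median went from -0.54 to -0.38 with the SE at 0.11, so they lost the call through a smaller fold, and the trend alone gave 33.3% of the fold, although sizes of called genes are inflated. A loss of chromosome 19 copies would lower its genes of every GC content, while the 110 with GC below the median had a median of 0.036 (bootstrap 95% interval 0.004 to 0.076). Genes of other chromosomes had 0.05 in that range. Above the median GC the 544 chromosome 19 genes had -0.105 (-0.127 to -0.087), against -0.063 (-0.07 to -0.057) elsewhere, a gap whose cause was not tested. With 10 splits of the 6 libraries too few for a share under 0.05, the real split, the 1 with as many, gave 185 calls and the highest other 4. A difference between codon 72 forms, between transfected lines, or in RNA quality beyond GC content stays open and untested.

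The hotspot comparison leans on 1 R273H P72 library in batch b2. The 866 genes called within batch b2 alone cannot come from a difference between batches, and 839 of them were among the 2376. For these 866 that single library as the cause is argued against. Of them, 95.4% had the same sign in other libraries, R273H P72 against R175H R72 in batch b1 (71.4% of uncalled genes). The rest of the 2376 calls were not covered by this check, so a batch difference stays open for them. The batch b1 check has 1 R175H R72 library, and the codon 72 form differs there along with the hotspot. The median log2 change in the direction of the calls was 0.412 there, against 0.647 in the batch b2 calls themselves. Between the R72 libraries of batch b2, with 1 of R273H, 74.8% of the calls had the same sign, against 58.9% of uncalled genes. Their median there was only 0.108. Of the 35 splits of the P72 libraries, 1, the real one, gave 2376 calls, and the highest other 2. This argues against a chance division of the libraries. The other splits mix the hotspots, so any difference between the lines widens their spread. Chance differences between transfected lines cannot be excluded, since replicates may come from the same line. The hotspot mutation and other differences between the transfected lines stay open, as the labels do not say how many lines each construct gave.

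Of 61 measures over the 4 R273H P72 libraries, 6 had 1 library far from the others, where chance gives about 1 in 20, or 3. Replicate 1, the only one in batch b2, had a GC slope of -0.062 (others 0.039 to 0.052). It also had 32.3 CPM of CDK2AP1 (2.77 to 6.23), 89.5 of JKAMP (23.7 to 31.4) and 130 of SLC44A1 (66 to 75.7). Replicate 2 had 32.9 CPM of SPTLC1 (27.7 to 28.1). Replicate 3 had 104 CPM of UPP1 (78.5 to 80.3).

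The R72 effect differed between R273H and R175H, by the test of the difference, by -1.01 for TUBA1B, -4.38 for TRPM8, 1.08 for MAF1, 0.98 for SNHG25 and -1.28 for SMIM11B on the log2 scale. Each rests on 1 R273H R72 library.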

How the results depend on the processing

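The GC-content correction, alone and in batch b2, was chosen after seeing the data; the other alternatives were planned. Calls over both mutants (35) became 22 with library totals, 348 without a filter, 140 by DESeq2, 2 without a batch term, 9 after GC correction, 12 in batch b2 and 2 with both. R72 on R175H (185) gave 564 without a filter, 333 by DESeq2, 6 without a batch term and 6 in the R175H libraries alone, 35 after GC correction and 58 with that in batch b2. R72 on R273H (0) gave 137 without a filter, 112 by DESeq2, 2 by limma-voom and 1 in batch b2. Its difference from R175H (5) gave 196, 138 and 12, with 1 without a batch term and 1 after GC correction. The hotspot count (2376) became 866 in batch b2 and 589 there after GC correction, which leaves fewer libraries. Without a batch term it was 2395 with 1378 genes shared, and TSFM reversed, from 0.54 to -0.17. Where no construction shows it, the cause was not tested.

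Leaving out each library gave 2 to 196 calls over both mutants, 24 to 272 for R72 on R175H, 0 to 6 on R273H, 0 to 48 for their difference and 1214 to 2463 for the hotspots. Over both mutants, omission gave 9 (R175H P72 replicate 1), 3 (replicate 2), 2 (R175H R72 replicate 2), 87 (replicate 4), 22, 17 and 18 (R273H P72 replicates 1, 3 and 4) and 196 (the R273H R72 library). On R175H it gave 52 without R175H P72 replicate 2, 24 without R175H R72 replicate 2 and 108 without R273H P72 replicate 3, and for the hotspots 1214 without R175H R72 replicate 1 and 1253 without R273H P72 replicate 1. For R72 on R273H it gave 6 without R175H P72 replicate 4, 2, 1 and 3 without R175H R72 replicates 1, 2 and 4, and 3 and 2 without R273H P72 replicates 1 and 4. For the difference it gave 11, 1 and 34 without R175H P72 replicates 1, 2 and 4, 15, 0 and 2 without R175H R72 replicates 1, 2 and 4, and 48, 18, 3 and 2 without R273H P72 replicates 1 to 4. Without the R273H R72 library the R273H effect and the difference could not be fitted.

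Replicate numbers showed no clear pairing of libraries: 1 of 9 same-number pairs correlated above 0.1 (r -0.61 to 0.25). Most of these pairs set a batch b1 against a batch b2 library and batch was not removed, so this check cannot exclude pairing. With the number as a replicate block the counts were 26, 81, 2, 2 and 1776 in the order above, and 4 in the R175H libraries alone. RLE scaling and the stricter filter left all counts within 1.5 times, and no other call of a named gene reversed. With a library left out PPARGC1A, never called, ran from -0.12 to 0.30 over both mutants and from -0.37 to 0.04 on R175H. Of the 135 list tests 22 lost their call with an estimated correlation and 19 by fry. Changes below 1.5-fold lie near the limit of this depth.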

Other observations

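The tests of HBD were chosen after the result was seen, and the test of splits over both mutants was planned.

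HBD (ENSG00000223609), the delta-globin gene, stood apart by hotspot in every library. It had 477 to 704 CPM in the 6 R175H libraries and 231 to 322 CPM in the 5 R273H libraries, from 2557 to 7872 counts. The codon 72 form did not part the libraries in this way. HBB had at most 0.356 CPM and HBE1 at most 2.07 CPM.

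Erythroid transcription as the source of HBD is argued against, since 11 other globin and erythroid genes together reached at most 0.782% of the HBD level in any library. A batch difference is argued against, since the lowest R175H library was 1.77 times the highest R273H library within batch b2. Expression constructs can carry globin elements, and the ratio of 2.19 within batch b1 is what such an element could give, but the construct sequence was not analysed here, so this cannot be told apart from transcription of the HBD locus or from reads shared with another transcript. The hotspot mutation itself stays open as well.

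For R72 against P72 over both mutants, 1 of 100 splits drawn from 330, the real one, gave 35 calls. The highest other gave 21, and 1 split was not estimable. This argues against a chance division of the libraries. It cannot exclude chance differences between transfected lines, since replicates may come from the same line.

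The R72 effect on R175H was also looked for in the R273H libraries of batch b2, 1 against 1 and without a test. Of 136 genes called on R175H in that batch, 74 had the same sign there (54.4%, against 48.9% of uncalled genes). For the genes called on R175H in that batch after GC correction it was 33 of 58 (56.9%, against 47.7%). The R273H values were not GC-corrected in either case.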
